A study of Mus musculus with 2 samples.

How the data were processed

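Cells of pooled gastrocnemius muscle were sorted into a SPiDER-βGal positive and a SPiDER-βGal negative fraction. Per the labels' protocols, the dyes 7-AAD and Hoechst were used to exclude debris and enrich nucleated cells, and libraries were made with the 10x Genomics GEM-X 3' chemistry and sequenced on a NovaSeq X instrument. The submitters' processing notes name Cell Ranger 9.0.0 and the mouse build GRCm39. The annotation release, the settings of the cell calling, any later filter and any treatment of doublets are not given in the sources used here.

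The files used here hold text and no measurement. As deposited by the authors, each library has 1 list of barcodes, in which every barcode has 16 bases and the same suffix, and 1 list of genes with the Ensembl identifier, the symbol and the feature type. The UMI counts that would go with these lists were not analysed here, so UMI totals per library and per cell are not reported. For the same reason 4 of the results planned before the data were examined were not computed, namely cell type shares, expression over all cells, expression within cell types and differences of gene lists between gates.

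Groups were taken from the sample titles, with 1 library per gate. No group was compared by a statistical test. The lists were read with Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1. Barcodes were counted per line and compared between gates by exact match after the suffix was removed. Shares have 95% exact Clopper-Pearson intervals. The size of a barcode set from which both lists were drawn was computed as the product of the list lengths divided by the number of shared sequences, with an exact Poisson interval for that number. This calculation was tested on simulated data, where the interval held the true size in 20 of 20 pairs of lists. The simulated lists were independent random draws from a common set, as the calculation assumes. The test therefore checks the arithmetic and cannot show whether the real lists meet that assumption.

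A comparison with 100 random shuffles of the gate labels over the barcodes had been planned as the chance level of shared sequences. It gave a median of 73 shared sequences (range 59 to 90), but its outcome is fixed by the data, because no sequence repeats within a list and a shuffle can only put some shared sequences on 1 side. It is not used as a chance level.

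Genes were matched by symbol to lists of functions and cell types fixed before the data were examined, with 162 genes in all and none in more than 1 list. Only genes of these lists are named. The reference annotation at hand was GENCODE M21 on GRCm38, another build than the one the submitters name, so no coordinates are given. Of the 33696 gene identifiers, 31961 (94.9%) were in its table of names, and 2587 of those had another symbol there. Symbols are those of the counted gene list.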

Results

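The samples were 2 single-cell RNA-seq libraries of cells from the gastrocnemius, the large superficial calf muscle, of wild-type C57BL/6J mice about 26 months old that had gone through 14 days of hindlimb unloading. Unloading takes body weight off the hind legs and is a standard way to cause disuse atrophy. The labels call the sampling point RL14 without spelling it out, and the series title speaks of recovery after disuse. Whether the muscles were loaded again before sampling, and for how long, is not stated in the labels. Muscles of 10 mice per group were pooled, and the cell suspension was sorted by flow cytometry on SPiDER-βGal. SPiDER-βGal is a substrate that becomes fluorescent when β-galactosidase cleaves it. High β-galactosidase activity is a widely used marker of senescence, the lasting arrest of the cell cycle, but cells rich in lysosomes, such as macrophages, can carry it too. One library was made from the SPiDER-positive gate and 1 from the SPiDER-negative gate. The comparison that this design implies is between the positive gate, which the labels call senescent, and the negative gate, which they call non-senescent. Whether the cells of either gate were senescent was not tested here. With 1 library per gate it has no replicates, and no p-value is given for any difference between gates.

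The values reported here are the cell barcodes and the gene lists of the 2 libraries. The UMI counts per gene and cell were not analysed here. No expression level, cell type share or depth per cell is therefore given, and no gene is described as higher or lower in either gate.

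The SPiDER-positive library held 19284 cell barcodes and the SPiDER-negative library held 24560, a ratio of 1.27 negative to positive. The deposited lists are marked as filtered, and how barcodes were chosen as cells is not given in the sources used here. The labels state neither the number of cells sorted through each gate nor the number loaded per library. The ratio compares the 2 libraries and does not measure the share of SPiDER-positive cells in the muscle.

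The barcode sequences were compared between gates. No sequence occurred more than once within either list. The lists had 147 sequences in common, which was 0.762% of the positive barcodes (95% exact Clopper-Pearson interval 0.644% to 0.895%) and 0.599% of the negative barcodes (0.506% to 0.703%). These intervals cover counting error only. The gates were separate sorted fractions made into separate libraries, and droplet kits draw the barcodes of every library from a common set. A sequence seen in both lists is therefore no evidence of a cell present in both gates. The kit's own barcode list, whose size would set a chance level for the number of shared sequences, was not used here, and the count was not tested against one.

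Both libraries were counted against the identical list of 33696 mouse genes. Every entry was of the gene expression type, so the list had no antibody or hashtag features. Mitochondrially encoded genes made up 13 of the entries. A further 248 entries carried an Ensembl identifier in place of a symbol, and 26 symbols were shared by more than 1 entry.

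The genes fixed in advance for comparing the gates were all in the counted list, each under a symbol of its own. Their presence describes the list used for counting and is not a result about either gate. Of 85 genes in the 8 lists of functions, 85 were present. The senescence arrest list had 8 of 8 genes, among them Cdkn1a (ENSMUSG00000023067) and Cdkn2a (ENSMUSG00000044303), which encode inhibitors of cyclin-dependent kinases, and Glb1 (ENSMUSG00000045594), which encodes lysosomal β-galactosidase. The secretory list had 23 of 23 genes, among them the cytokine genes Il6 and Il1b and the chemokine gene Ccl2. The lysosome list had 15 of 15 genes, among them Lamp1 and the cathepsin genes Ctsb and Ctsd. The iron and redox, proliferation and matrix lists each had 8 of 8 genes, with Hmox1, Mki67 and Col1a1 as examples. The interferon list had 6 of 6 genes and the dissociation stress list 9 of 9, with Isg15 and Fos as examples.

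The 19 lists of cell type markers had 77 of 77 genes in the counted list. They included 6 macrophage markers such as Adgre1 and C1qa, 5 markers of fibro-adipogenic progenitors such as Pdgfra and Dcn, and 5 satellite cell markers such as Pax7 and Myf5. There were 4 endothelial markers, such as Pecam1 and Cdh5, and 4 neutrophil markers, such as S100a8 and S100a9. Presence in the list means that a gene had an entry of its own and says nothing about whether either gate expressed it. Whether its reads could be told apart from those of similar genes was not examined.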

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

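All alternatives reported here were chosen before the data were examined. Counting distinct sequences in place of lines left 19284 positive and 24560 negative barcodes. No sequence occurred more than once within either list, so this alternative could not change the counts and says nothing about stability. Allowing up to 1 base difference also gave 147 positive barcodes with a match in the negative list. Within each list, 0 barcodes were within 1 base of another. Barcodes this close may be absent from the common set as well, so the equal count says little about stability. Reverse complementing one list gave 0 shared sequences, against 147 in the orientation given. Both lists are written in the same orientation, so this alternative was bound to lose matches and says little about stability. Matching symbols without regard to case could not raise the count of listed genes, since 162 of 162 were already found as written. A further 7 settings, on cell filters, clustering resolution, doublets, weighting, scaling and low counts, had also been planned and were not run, because they need UMI counts, which were not analysed here. No replicate could be left out with 1 library per gate. No paired analysis was possible because each gate has 1 library and no result comes from a test.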

Other observations

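If the 2 barcode lists were independent random draws from a common set, the 147 shared sequences put the size of that set at 3221871 sequences (95% interval 2741200 to 3813401, counting error only). Within each list, 0 barcodes were within 1 base of another barcode of the same list. Sequences this close may be absent from the common set, so this count is not read as a property of these libraries. No hypothesis about the cells of either gate was tested.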
